A study of Fervidobacterium islandicum with 4 samples.

How the data were processed

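The series holds RNA sequencing of *Fervidobacterium islandicum* AW-1 grown with glucose, feather, peptone or tryptone, 1 GEO sample per condition. Per the labels' protocols, total RNA was extracted with a column kit and made into libraries with a TruSeq RNA kit, and the series design text gives exponential growth, duplicates and an Illumina HiSeq sequencer. The aligner, the counting tool, the genome build and the annotation version are not given in the sources used here, and whether counting used strand is not given either, so reads of overlapping or near-identical genes, transposase genes among them, may be shared.

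The authors deposited 5 tables, each of 1 pair of conditions, with 2209 genes, and none of them pairs peptone with tryptone. Per the file headers, each table holds FPKM values that the authors computed per library and averaged over the libraries of a condition. Per the file headers, the authors also gave each gene 2 signal values, counts scaled by median-of-ratios (RLE) and by TMM factors of that pair, averaged in the same way. The authors' p-values, per the file headers, are those of DESeq2 and edgeR with Bonferroni and FDR columns; only counts of genes under an FDR of 0.05 were taken from them, with the direction from the RLE ratio. Gene names came from the deposited annotation text, which has a line for 2038 of the genes; 1541 had an informative product name. Sentences on function were left out of the names. Neighbouring genes and runs of genes were taken from the order of the identifiers, and no genome was used here to check them. This reading was refined after gene values had been seen, which took FIAW1_08300 out of the list of ferredoxin-linked and oxoacid oxidoreductases.

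The design fixed before the data were examined treated each condition as 1 value. Values were log2(FPKM + 1), a gene entered a comparison with at least 10 FPKM in 1 of the 2 conditions, and genes with a difference of at least 1 were counted, with no test. A fold on this scale understates the change of low genes. The 6 pairs of conditions were compared. For 21 gene lists fixed as search patterns, the median log2 difference was set against 10000 random lists of the same size matched on mean expression in 10 bins, which describes these libraries and is not a test; lists with at least 5 members were used. All lists are described for feather against glucose, and those described for the other pairs were chosen after the values had been seen. The patterns let in some genes that do something else, and only some of these are named as such. The pattern of flagella and chemotaxis also matches the word branched, and so lets in genes of branched-chain amino acid transport. List counts and medians were not cleared of such genes. Named genes followed a rule: the 8 highest and 8 lowest genes with a product name for feather against glucose and the 4 highest and 4 lowest for the other 5 pairs, the 2 members (1 for the other pairs) of each described list furthest apart, the peptidase gene of highest mean, and the 5 genes highest and 5 lowest on feather against all 3 other conditions. Not every gene that this rule selects is printed.

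The means turned out to hold more than 1 value per condition. Each scaled mean is a sum of the counts of 2 libraries times 2 fixed steps, and the tables of different pairs use different steps, so the counts of both libraries could be solved for. All values came out whole within 0.01, the largest distance being 0.0035. Size factors recomputed from the counts matched the deposited steps within a relative 1e-10 in all 5 tables. FPKM, which was not used in this step, gave ratios with a median misfit between 0.00012 and 0.00014 (log2) after a weight was fitted for each library. Because these weights are free, this check cannot tell which split of the means into 2 libraries is right. That choice rests on the whole counts and the size factors. On simulated data the step returned all genes in each condition.

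After the data were seen, a test was added on these counts: limma-voom (limma 3.58.1, R 4.3.3), 1 fit per pair with 4 libraries, library sizes scaled by median of ratios, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. This departs from the fixed design, which had no test. Errors after ± are standard errors from this fit, n is 2 libraries per condition, and "rose" and "fell" refer to genes past this threshold. Counts "adjusted over the list alone" adjust the same p-values within a list. On simulated counts with 200 changed genes and each condition's own spread, it called 39% of 2-fold and 94% of 4-fold changes for feather against glucose (2132 genes), 99% and 100% for peptone against glucose (2099), 100% and 100% for tryptone against glucose (2093), 28% and 97% for feather against peptone (2131), 34% and 98% for feather against tryptone (2131), and 99% and 100% for peptone against tryptone (2092). Between 1.5% and 4.3% of those calls were of unchanged genes. The simulated genes varied independently, with 1 spread for all genes of a condition, whereas whole gene lists differed together between the real feather libraries. These percentages therefore describe the simulated setting and not the error rate or the power on the real counts.

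The alternatives fixed in advance were pseudocounts of 0.1 and 10, no filter, a minimum of 50 FPKM, median-of-ratios scaling of FPKM, FPKM scaled to equal totals, the authors' RLE and TMM values, a 4-fold threshold and each column of a condition alone. The deposited columns are means, so the last of these was applied to the recovered libraries, a choice made after the data were seen. The other alternatives added later vary the limma test: limma-trend, library totals, 1 variance weight per condition, all 8 libraries in 1 fit, no filter, a minimum of 50 FPKM and each library left out. A condition left with 1 library is then assumed to vary like the other condition. For a gene with 0 counts in a condition, a fold is given as a lower bound with 3 counts as the floor; with 1 to 3 counts, the ratio has an exact binomial 95% interval. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A workbook that repeats 2 of the pair tables was not used here.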

Results

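Messenger RNA of *Fervidobacterium islandicum* AW-1, an anaerobic thermophilic bacterium known to break down feather keratin, was sequenced from cells grown with glucose, native feather, peptone or tryptone. Peptone and tryptone are soluble protein digests, and feather is a solid protein. The labels list 1 sample for each of the 4 conditions, and the series design text says that the material was sequenced in duplicate. The deposited means gave back the read counts of 2 libraries per condition, called A and B here, where A is only the one with the higher total. Total counts were 23147220 and 21374938 in glucose, 16765440 and 8464552 in feather, 12251268 and 11544547 in peptone, and 15788744 and 11656615 in tryptone. Of the 2209 genes listed, 60 were at 0 in every condition, among them all 47 tRNA genes and all 6 rRNA genes. Nothing in the labels says that the duplicates came from separate cultures, so every p-value below measures only the spread between these libraries, which may be technical.

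The libraries of a condition differed to very unequal degrees. The scatter of the log2 ratio between libraries, as a robust SD across genes, was 0.080 in glucose, 0.240 in peptone, 0.169 in tryptone and 0.556 in feather. In feather 200 genes lay at least 2-fold apart between the libraries, against 1 gene in glucose, 31 in peptone and 47 in tryptone. Whole gene lists differed between the feather libraries. Relative to all genes, the median log2 ratio of library A to B was 0.65 for the glycolysis and gluconeogenesis and the ribosomal protein lists, 0.44 for oxygen and peroxide defence, 0.40 for iron-sulfur and iron transport and 0.38 for ferredoxin-linked and oxoacid oxidoreductases, and it was lowest for glycoside hydrolases (-0.34). Comparisons with feather therefore carry a wider error than those among the other 3 conditions.

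**Figure D1:**
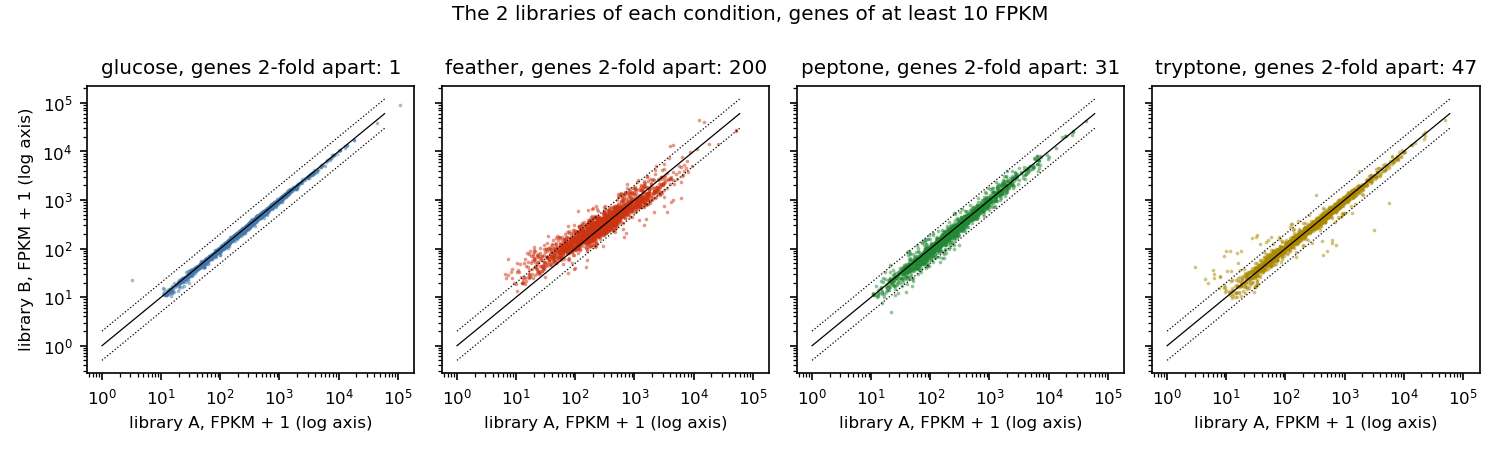
Each point is a gene of at least 10 FPKM in that condition, with its FPKM plus 1 in library A on the x axis and in library B on the y axis, both on log axes. The solid line marks equal FPKM and the dotted lines 2-fold differences, and the titles count the genes at least 2-fold apart after the median ratio is set to 1, of which there were 200 in feather.

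In FPKM, the median gene differed between the conditions of each pair. The median log2 FPKM difference over the genes tested was 0.18 for feather against glucose, -0.37 for peptone against glucose, -0.22 for tryptone against glucose, 0.50 for feather against peptone, 0.38 for feather against tryptone and -0.13 for peptone against tryptone. The limma fold changes use median-of-ratios scaling, which by its construction brings these medians to between -0.02 and 0.01. List medians are given relative to all genes. Both treat the median gene as unchanged. The medians cannot tell a shift of all genes together from changes in many genes. Named genes of a pair of conditions were ranked by the difference in log2(FPKM + 1), outside the lists only among genes with a product name, so their order by limma can differ.

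The first comparison asked how growth on feather differed from growth on the sugar. Among the largest increases on feather was a run of peptide transport genes, where a run or a neighbour is by the order of identifiers and was not checked on a genome. The gene of the peptide ABC transporter substrate-binding protein FIAW1_04780 stood at 1879 FPKM on feather and 19.0 FPKM on glucose, a log2 fold change of 6.42 ± 0.40 (SE, limma, n = 2 libraries per condition, adjusted p = 0.0034). The permease gene FIAW1_04770 rose by 5.47 ± 0.55 (limma adjusted p = 0.0075), and the ArsR family regulator gene FIAW1_04790 by 5.70 ± 0.43 (adjusted p = 0.0041). The radical SAM protein gene FIAW1_04830 went from 32.2 to 1238 FPKM, a log2 fold change of 5.10 ± 0.18 (limma adjusted p = 0.0023). A second run held the phosphoenolpyruvate carboxykinase gene FIAW1_18900, whose enzyme opens gluconeogenesis, with a log2 fold change of 5.08 ± 0.40 (limma adjusted p = 0.0045). Next in identifier order were the transcriptional regulator gene FIAW1_18910 at 5.82 ± 0.93 (limma adjusted p = 0.019) and the epimerase gene FIAW1_18920 at 5.33 ± 0.70 (adjusted p = 0.014).

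The transposase gene FIAW1_11150 had the highest difference in log2(FPKM + 1) among genes with a product name, with 350.2 FPKM on feather and 0.04 on glucose. It stood at 110.9 and 589.5 FPKM in the feather libraries. The gene did not pass the test (12.36 ± 3.61, limma, adjusted p = 0.062), and the source of this wide error was not tested. It held 6603 counts over both feather libraries and 1 count over both glucose libraries, and the ratio of counts per total was 1.17e+04 with an exact 95% interval from 2.09e+03 to 4.6e+05, which covers counting error only.

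Large decreases on feather included glycerol, phosphate and fatty acid genes. The glycerol dehydrogenase gene FIAW1_19310 went from 13675 FPKM on glucose to 783 on feather, a log2 fold change of -4.60 ± 1.07 (SE, limma, adjusted p = 0.041). The phosphate ABC transporter genes FIAW1_18420 and FIAW1_18430 had log2 fold changes of -4.33 ± 0.47 and -3.97 ± 0.32 (limma adjusted p = 0.009 and 0.0048). The fatty acid synthesis genes FIAW1_09140, for a hydroxyacyl-ACP dehydratase, and FIAW1_09150, for a 3-oxoacyl-ACP synthase, had log2 fold changes of -3.60 ± 0.17 and -3.47 ± 0.17 (limma adjusted p = 0.0024 for both). The nitronate monooxygenase gene FIAW1_09130 fell by 3.51 ± 0.14 (limma adjusted p = 0.0023). The alcohol dehydrogenase gene FIAW1_17850 and the acyl-CoA dehydrogenase gene FIAW1_11950 had log2 fold changes of -3.88 ± 0.62 and -3.51 ± 0.44 (limma adjusted p = 0.019 and 0.012).

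**Figure D2:**
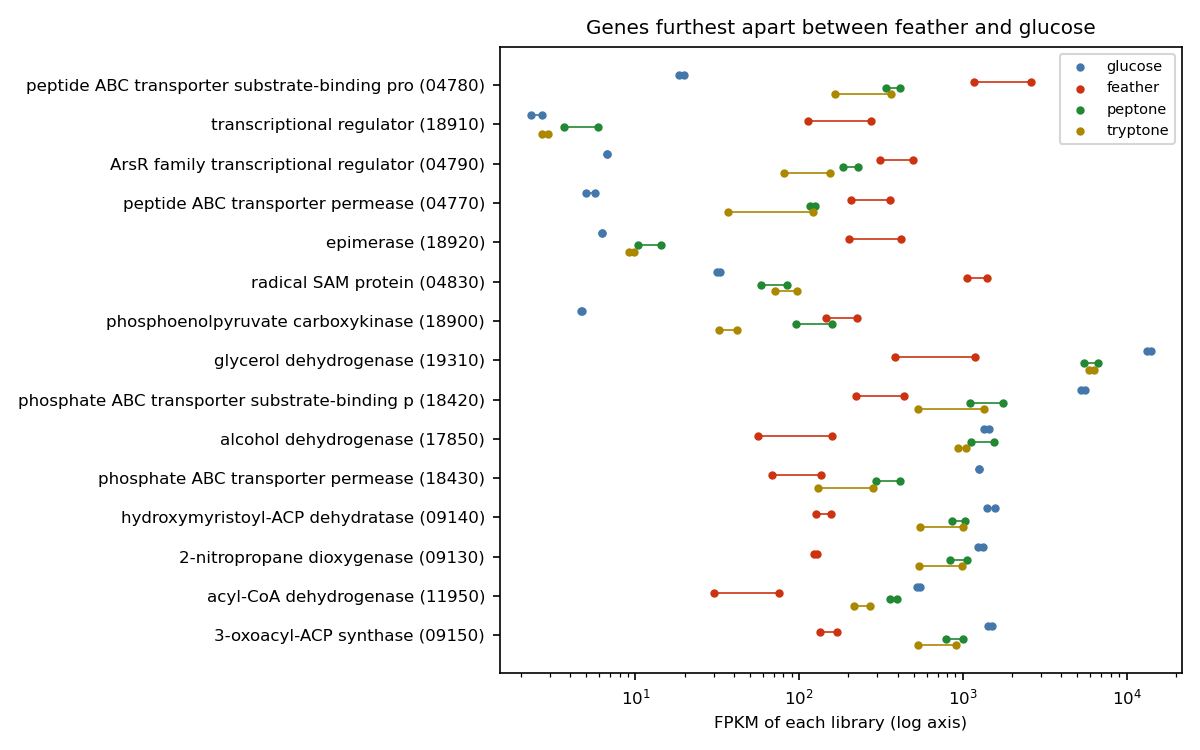
FPKM of each library, on a log x axis, of the 15 genes with a product name that lay furthest apart between feather and glucose; the transposase gene FIAW1_11150 is left out because it was at 0 in some libraries. A line joins the 2 libraries of a condition, and the substrate-binding protein gene FIAW1_04780 stood at 1166 and 2591 FPKM in the feather libraries against 19.7 and 18.3 in those of glucose.

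Among the lists of genes for uptake, 20 of the 39 sugar transporter genes rose on feather and 2 fell (23 and 2 adjusted over the list alone). The list's median log2 difference lay 1.76 above that of all genes, at percentile 100 of the random lists matched on expression. Its leading members were the ribose transport genes FIAW1_01880 and FIAW1_01900, with log2 fold changes of 4.61 ± 0.73 and 4.51 ± 0.23 (limma, adjusted p = 0.019 and 0.0024). Of the 33 peptide transporter genes, 13 rose and 1 fell (17 and 3 adjusted over the list alone), at percentile 93.2. Of the 21 amino acid transporter genes, 11 rose and 4 fell (11 and 6 adjusted over the list alone), at percentile 98.9. There the genes of the branched-chain amino acid binding proteins FIAW1_20900 and FIAW1_20890 rose by 3.25 ± 0.38 and 3.11 ± 0.28 (limma adjusted p = 0.011 and 0.0067).

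Of the 36 peptidase genes, 8 rose and 4 fell (8 and 5 adjusted over the list alone), and the list's median lay at percentile 83.3. The serine protease gene FIAW1_13170 went from 515 to 3677 FPKM (log2 fold change 2.63 ± 0.33, limma, adjusted p = 0.012), and the lysyl aminopeptidase gene FIAW1_09000 from 16.3 to 80.4 FPKM (2.04 ± 0.27, adjusted p = 0.014). The peptidase gene with the highest mean, that of the extracellular subtilisin-type protease FIAW1_13830, stood at 6018 FPKM on feather and 8030 on glucose, and did not pass the test (-0.64 ± 0.29, limma adjusted p = 0.15). Among 10 chaperone and ATP-dependent protease genes none rose and 2 fell, over all genes and adjusted over the list alone, while the median lay at percentile 97.8. The gene of the membrane protease HtpX, FIAW1_18850, fell by 1.35 ± 0.12 (limma adjusted p = 0.0068), and the small heat shock protein gene FIAW1_04130 stood at 214 against 95.5 FPKM without passing (adjusted p = 0.24).

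Genes for the use of amino acids changed in several lists. Of 14 ferredoxin-linked and oxoacid oxidoreductase genes, 6 rose and 6 fell, over all genes and adjusted over the list alone (percentile 93.7), in a list whose median differed by 0.38 between the feather libraries. The CoA transferase gene FIAW1_06210 and the ketoisovalerate ferredoxin reductase gene FIAW1_04220 rose by 3.84 ± 0.22 and 3.59 ± 0.12 (limma, adjusted p = 0.0032 and 0.0023). FIAW1_06210 entered the list by its name and is not annotated as an oxidoreductase. Of 28 genes of aminotransferases and amino acid breakdown, 10 rose and 3 fell (11 and 4 adjusted over the list alone, percentile 98.5). The lysine 2,3-aminomutase gene FIAW1_06250, for an early step of lysine fermentation, rose by 3.12 ± 0.12 (limma adjusted p = 0.0023). The sugar aminotransferase gene FIAW1_19050, which belongs to sugar metabolism, did not pass (limma adjusted p = 0.054). Of 29 amino acid biosynthesis genes, 9 rose and 5 fell (10 and 6 adjusted over the list alone, percentile 39.5). The 2 leading members, FIAW1_20610 and FIAW1_20630, rose by 4.85 ± 0.32 and 4.54 ± 0.31 (limma adjusted p = 0.0034 and 0.0035), and FIAW1_20630 is annotated as a thiolase that takes part in ornithine breakdown.

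In central metabolism, 4 of 17 glycolysis and gluconeogenesis genes rose and 6 fell (5 and 8 adjusted over the list alone, percentile 32.6), in a list whose median differed by 0.65 between the feather libraries, with the fructose bisphosphatase gene FIAW1_16210, of gluconeogenesis, at 398 against 62.3 FPKM (limma, adjusted p = 0.0024). Of 32 glycoside hydrolase genes, 12 rose and 6 fell (13 and 7 adjusted over the list alone, percentile 52.8, feather library A at -0.34 relative to B), among them the hexosaminidase gene FIAW1_10670 and the beta-galactosidase gene FIAW1_08710, which rose by 3.40 ± 0.66 and 3.28 ± 0.41 (limma adjusted p = 0.028 and 0.012). Of 24 purine and pyrimidine synthesis genes, 13 fell and none rose (18 fell and 2 rose adjusted over the list alone, percentile 0.0). The purine gene FIAW1_14210 fell by 3.45 ± 0.52 (limma adjusted p = 0.017), and FIAW1_02890, annotated as a ferredoxin-NADP reductase subunit, did not pass (adjusted p = 0.084).

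Sulfur and redox genes split. Of 15 cysteine, methionine and sulfur genes, 3 rose and 3 fell, over all genes and adjusted over the list alone, with the median at percentile 1.6. The S-adenosylmethionine decarboxylase gene FIAW1_17670 rose by 2.48 ± 0.27 (limma, adjusted p = 0.009), and the cysteine desulfurase gene FIAW1_17100 by 1.21 ± 0.11 (adjusted p = 0.0058). Of 11 thiol and disulfide genes, 3 rose and 1 fell, over all genes and adjusted over the list alone (percentile 57.5). They included the methionine sulfoxide reductase gene FIAW1_05780 (1.74 ± 0.15, limma adjusted p = 0.0061) and the peptide permease gene FIAW1_04770, which entered by its annotation as a glutathione transporter. Of 16 iron-sulfur and iron transport genes, 4 rose and 1 fell, over all genes and adjusted over the list alone (percentile 93.4, feather library A 0.40 above B), led by the Fe-S assembly gene FIAW1_17110 (2.66 ± 0.17, limma adjusted p = 0.0034) and the iron transport permease gene FIAW1_01780 (164 against 23.8 FPKM, adjusted p = 0.018). Of 26 hydrogenase and electron carrier genes, 5 rose and 3 fell (6 and 4 adjusted over the list alone, percentile 70.2), with FIAW1_04210, annotated as a formylmethanofuran dehydrogenase subunit, up by 3.75 ± 0.21 (limma adjusted p = 0.0032). The hydrogenase subunit gene FIAW1_08840 of that list lay the other way, at 867 against 6876 FPKM, without passing (limma adjusted p = 0.086). Of 9 oxygen and peroxide defence genes, 2 rose and 1 fell (2 and 2 adjusted over the list alone, percentile 86.4, feather library A 0.44 above B). The rubrerythrin gene FIAW1_20910 rose by 0.80 ± 0.19 (limma adjusted p = 0.041), and the peroxiredoxin gene FIAW1_18890 stood at 20006 against 9121 FPKM without passing (adjusted p = 0.15).

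Among the remaining lists, 33 of 70 flagella and chemotaxis genes rose and 7 fell (35 and 10 adjusted over the list alone, percentile 100). The largest differences in that list belonged to the amino acid binding protein genes FIAW1_20890 and FIAW1_20900, which are transport genes. The list's pattern matches the letters of CheD in the word branched, so it also holds other branched-chain amino acid transport genes, such as FIAW1_12860 and FIAW1_07170. These genes are in the amino acid transporter list too. The list was not counted without them, so its values do not describe motility genes alone. Of 49 ribosomal protein genes, 4 rose and 1 fell, and 0 did either adjusted over the list alone. Their median lay 0.33 above that of all genes (percentile 100), but at -0.065 without feather library A. The genes of S18 (FIAW1_02670) and L25 (FIAW1_09040), the members furthest apart, did not pass (limma, adjusted p = 0.099 and 0.19). Of 24 aminoacyl-tRNA ligase genes, 2 rose and 8 fell, over all genes and adjusted over the list alone (percentile 9.5), among them the glutamate ligase gene FIAW1_10090 (-1.26 ± 0.14, limma adjusted p = 0.0091) and the valine ligase gene FIAW1_07550 (-1.28 ± 0.22, adjusted p = 0.022). None of 11 cell surface and type IV pili genes passed, over all genes or adjusted over the list alone (percentile 26.8), and the S-layer gene FIAW1_09850 and the PilT gene FIAW1_07730 had limma adjusted p = 0.067 and 0.09. Of 95 CRISPR and mobile element genes, 3 rose and 23 fell, over all genes and adjusted over the list alone (percentile 5.5), with the transposase gene FIAW1_03500 down from 2203 to 508 FPKM (-2.30 ± 0.18, limma adjusted p = 0.0042).

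In all, 485 of 2132 genes were at least 2-fold higher on feather than on glucose by FPKM and 124 were at least 2-fold lower, a count with no test. The authors' RLE values gave 419 and 159. By limma, 406 genes rose and 336 fell (457 and 241 with library totals in place of median-of-ratios scaling), and the authors' deposited table holds 569 higher and 415 lower genes at a DESeq2 FDR under 0.05 and 552 and 331 at an edgeR FDR under 0.05. The limma counts were 136 and 36 without glucose library A and 148 and 39 without glucose library B, where the spread is then taken from feather, and 909 and 921 without feather library A and 866 and 847 without feather library B, where it is taken from glucose. Without a glucose library the calls of FIAW1_01510, FIAW1_07550, FIAW1_08710, FIAW1_08830, FIAW1_09000, FIAW1_10090, FIAW1_10670, FIAW1_17100, FIAW1_18850, FIAW1_19310 and FIAW1_20910 were lost, with limma adjusted p up to 0.38.

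The second comparison set peptone against glucose. The largest increases included a run with genes named after butyrate, whose substrates were not tested. The phosphate butyryltransferase gene FIAW1_04180 went from 23.4 to 1931 FPKM (log2 fold change 6.73 ± 0.11, SE, limma, n = 2 libraries per condition, adjusted p = 1.1e-05), and the butyrate kinase gene FIAW1_04190 from 28.2 to 1921 FPKM (6.45 ± 0.09, adjusted p = 1e-05). FIAW1_04200, annotated as a cobyric acid synthase, rose by 6.39 ± 0.13 (limma adjusted p = 1.4e-05), and the acyl-CoA hydrolase gene FIAW1_06220, also annotated as the 3-aminobutyryl-CoA ammonia lyase of lysine fermentation, by 6.19 ± 0.27 (adjusted p = 0.00011). Large decreases included those of the purine genes FIAW1_14190, FIAW1_14200 and FIAW1_14210 (-3.29 ± 0.28, -3.01 ± 0.20 and -2.81 ± 0.19, limma adjusted p = 0.00082, 0.0004 and 0.00044) and of the hydroxylamine reductase gene FIAW1_16660 (-2.59 ± 0.12, adjusted p = 0.00012).

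Of the 39 sugar transporter genes, 35 rose on peptone and 1 fell, over all genes and adjusted over the list alone (percentile 100), led by the xylose transport gene FIAW1_20400 (5.48 ± 0.31, limma, adjusted p = 0.00025). Of 33 peptide transporter genes, 21 rose and none fell, over all genes and adjusted over the list alone (percentile 100), with FIAW1_04770 up by 4.85 ± 0.15 (limma adjusted p = 5.2e-05). Of 21 amino acid transporter genes, 13 rose and 8 fell (percentile 99.6), and of 32 glycoside hydrolase genes 19 rose and 3 fell (percentile 98.3), over all genes and adjusted over the list alone. Of 28 genes of aminotransferases and amino acid breakdown, 17 rose and 3 fell, over all genes and adjusted over the list alone (percentile 100), and FIAW1_06250 rose by 5.92 ± 0.13 (limma adjusted p = 1.6e-05). Of 14 ferredoxin-linked and oxoacid oxidoreductase genes, 10 rose and 4 fell, over all genes and adjusted over the list alone (percentile 100). The list member furthest apart was the CoA transferase gene FIAW1_06210, not annotated as an oxidoreductase, which was up by 6.06 ± 0.25 (limma adjusted p = 0.0001). Of 49 ribosomal protein genes, 37 rose and none fell (38 and 0 adjusted over the list alone, percentile 99.8). The change was small: their median log2 FPKM difference was 0.138, or 0.504 relative to all genes, and 0 members were 2-fold higher. Most of that relative rise thus comes from the median difference of all genes. Of 23 purine and pyrimidine genes, 19 fell and none rose, over all genes and adjusted over the list alone (percentile 0.0). Of 36 peptidase genes, 11 rose and 8 fell, over all genes and adjusted over the list alone (percentile 86.4), with the peptidase M55 gene FIAW1_21560 up by 3.14 ± 0.29 (limma adjusted p = 0.0011) and FIAW1_13830 at 5910 against 8030 FPKM without passing (adjusted p = 0.42).

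By FPKM, 264 of 2099 genes were at least 2-fold higher on peptone and 193 at least 2-fold lower, and the authors' RLE values gave 333 and 70. By limma 678 rose and 611 fell (452 and 1155 with library totals), and the authors' deposited table holds 676 and 574 at a DESeq2 FDR under 0.05 and 669 and 573 by edgeR. The number that fell was 249 without glucose library A and 282 without glucose library B.

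The third comparison set tryptone against glucose. The run with the genes named after butyrate again led. FIAW1_04180 rose by 5.53 ± 0.08 (SE, limma, n = 2 libraries per condition, adjusted p = 4.9e-06), FIAW1_04190 by 5.35 ± 0.08 (adjusted p = 4.9e-06), FIAW1_04200 by 5.32 ± 0.13 (adjusted p = 1.7e-05) and the ketoisovalerate ferredoxin reductase gene FIAW1_04220 by 4.95 ± 0.07 (adjusted p = 4.9e-06). The purine genes FIAW1_14190, FIAW1_14200 and FIAW1_14210 had log2 fold changes of -3.01 ± 0.20, -2.78 ± 0.15 and -2.77 ± 0.11 (limma adjusted p = 0.00043, 0.00022 and 7.5e-05), and the phosphate permease gene FIAW1_18430 one of -2.46 ± 0.36 (adjusted p = 0.0038). Of 49 ribosomal protein genes, 48 rose and none fell, over all genes and adjusted over the list alone (percentile 100), with the S7 gene FIAW1_14660 up by 1.42 ± 0.06 (limma adjusted p = 0.00013). Their median log2 FPKM difference was 0.588, or 0.805 relative to all genes, and 1 member was 2-fold higher. Of 39 sugar transporter genes, 22 rose and 3 fell, over all genes and adjusted over the list alone (percentile 99.9). The member furthest apart there, the carbohydrate-binding protein gene FIAW1_05250, did not pass (limma adjusted p = 0.091). On tryptone, 16 of the 28 genes of aminotransferases and amino acid breakdown rose and 3 fell (the same over the list alone, percentile 99.9). In the ferredoxin-linked and oxoacid oxidoreductase list, 10 of 14 genes rose and none fell (11 and 0 adjusted over the list alone, percentile 99.8). The peptide transporter list was mixed on tryptone, where 13 of 33 genes rose and 9 fell, over all genes and adjusted over the list alone (percentile 73.5). Of 21 amino acid transporter genes, 9 rose and 8 fell (10 and 8 adjusted over the list alone, percentile 99.1), and of 32 glycoside hydrolase genes 13 rose and 4 fell, over all genes and adjusted over the list alone (percentile 94.8). Of 94 CRISPR and mobile element genes, 55 fell and 6 rose, over all genes and adjusted over the list alone (percentile 0.0), with the transposase gene FIAW1_20300 at a log2 fold change of -2.32 ± 0.10 (limma adjusted p = 0.00013). In the purine and pyrimidine list, 16 of 23 genes fell and 1 rose (the same over the list alone, percentile 0.0). In the peptidase list, 9 of 36 genes rose and 13 fell (the same over the list alone, percentile 75.9). The protease gene FIAW1_13830 fell from 8030 to 5223 FPKM (-0.42 ± 0.09, limma adjusted p = 0.014).

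By FPKM, 173 of 2093 genes were at least 2-fold higher on tryptone and 131 at least 2-fold lower, and the authors' RLE values gave 231 and 81. By limma 666 rose and 638 fell (479 and 1019 with library totals), and the authors' deposited table holds 716 and 650 at a DESeq2 FDR under 0.05 and 562 and 459 by edgeR. The limma counts were 363 and 223 without glucose library A and 369 and 246 without glucose library B, and the calls of FIAW1_13830 and FIAW1_18430 were then lost (adjusted p up to 0.14).

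**Figure D3:**
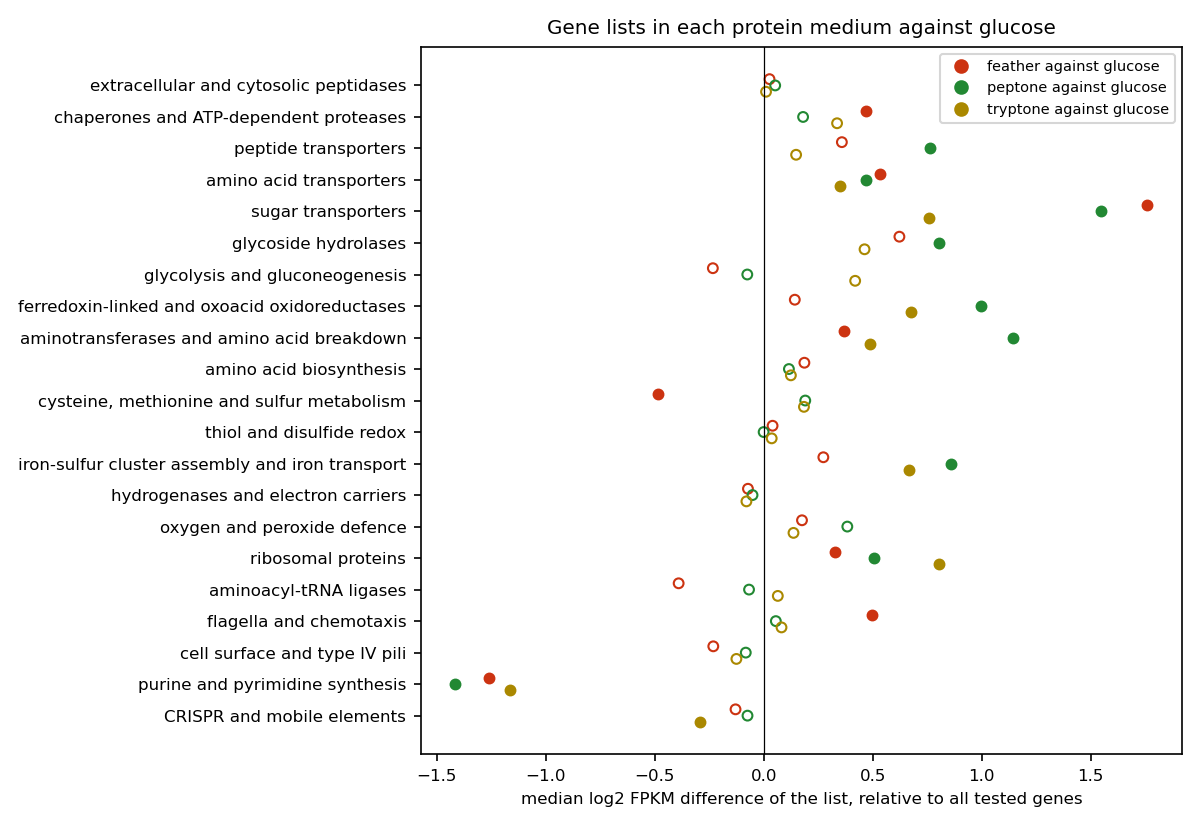
Median log2 FPKM difference of each of the 21 gene lists, relative to the median of all genes tested, for feather, peptone and tryptone against glucose. Filled points lie outside the middle 95% of 10000 random lists matched on expression and open points within it; sugar transporters lay above 0 and purine and pyrimidine synthesis below 0 in all 3.

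The fourth comparison set the solid protein against peptone. The regulator gene FIAW1_18910 and the epimerase gene FIAW1_18920 were again among the highest on feather, with log2 fold changes of 4.63 ± 0.86 and 4.09 ± 0.56 (SE, limma, n = 2 libraries per condition, adjusted p = 0.024 and 0.011). The transposase gene FIAW1_11150 held 6603 counts on feather and 2 on peptone (limma adjusted p = 0.045), a ratio of 3.11e+03 with an exact 95% interval from 862 to 2.57e+04 for counting error. The pyridoxamine phosphate oxidase gene FIAW1_18050 stood at 94.3 against 3.61 FPKM (5.14 ± 1.19, limma adjusted p = 0.041). Its peptone libraries A and B stood at 7.2 and 0.0 FPKM, so the peptone mean came almost wholly from library A. The glutamate dehydrogenase gene FIAW1_14020 stood at 2328 FPKM on feather and 25408 on peptone (-3.96 ± 0.34, limma adjusted p = 0.0036). The sugar transporter substrate-binding protein gene FIAW1_20410 (-3.87 ± 0.35, limma adjusted p = 0.0036), the radical SAM gene FIAW1_03550 (-3.99 ± 0.28, adjusted p = 0.0032) and the alcohol dehydrogenase gene FIAW1_17850 (-4.16 ± 0.56, adjusted p = 0.01) were also lower on feather.

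Of 14 ferredoxin-linked and oxoacid oxidoreductase genes, 12 fell on feather relative to peptone and none rose (13 and 0 adjusted over the list alone, percentile 0.2, feather library A 0.38 above B). Of 28 genes of aminotransferases and amino acid breakdown, 11 fell and none rose (13 and 0 adjusted over the list alone, percentile 0.0). Of 70 flagella and chemotaxis genes, 22 rose and none fell (28 and 0 adjusted over the list alone, percentile 100), with the hook capping gene FIAW1_00300 up by 1.94 ± 0.37 (limma, adjusted p = 0.026). That list again includes branched-chain amino acid transport genes and was not counted without them. Of 36 peptidase genes, 3 rose and 4 fell, over all genes and adjusted over the list alone (percentile 38.4), with FIAW1_09000 up by 2.38 ± 0.37 (limma adjusted p = 0.016). Of 39 sugar transporter genes, 2 rose on feather relative to peptone and 9 fell (4 and 9 adjusted over the list alone, percentile 0.0), and of 32 glycoside hydrolase genes 1 rose and 5 fell (2 and 6 adjusted over the list alone, percentile 0.0, feather library A at -0.34 relative to B). Of 33 peptide transporter genes, 2 rose and 4 fell (4 and 9 adjusted over the list alone, percentile 48.0), and of 21 amino acid transporter genes 4 rose and none fell (5 and 0 adjusted over the list alone, percentile 100).

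By FPKM, 508 of 2131 genes were at least 2-fold higher on feather than on peptone and 111 at least 2-fold lower, but the authors' RLE values gave 250 and 210. By limma 148 rose and 222 fell (508 and 125 with library totals), and the authors' deposited table holds 322 and 336 at a DESeq2 FDR under 0.05 and 339 and 273 by edgeR. The limma counts were 16 and 58 without peptone library A, 14 and 44 without peptone library B, 518 and 483 without feather library A and 376 and 453 without feather library B. Of the genes named here, the calls of FIAW1_00300, FIAW1_09000, FIAW1_11150, FIAW1_18050, FIAW1_18910 and FIAW1_18920 were lost without a peptone library, with limma adjusted p up to 0.23.

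The fifth comparison set feather against tryptone. FIAW1_18910 and FIAW1_18920 rose by 5.44 ± 1.02 and 4.57 ± 0.67 (SE, limma, n = 2 libraries per condition, adjusted p = 0.04 and 0.031). The ArsR family regulator gene FIAW1_02830 stood at 485 against 22.1 FPKM and the transposase gene FIAW1_11150 at 350.2 against 0.13, and neither passed (limma adjusted p = 0.071 and 0.082). Lower on feather were FIAW1_03550 (-3.89 ± 0.25, limma adjusted p = 0.011), the biotin synthase gene FIAW1_03530 (-3.56 ± 0.26, adjusted p = 0.014) and FIAW1_17850 (-3.60 ± 0.55, adjusted p = 0.031). The transposase gene's ratio of counts per total was 3.59e+03, with an exact 95% interval from 994 to 2.97e+04 for counting error. Of 14 ferredoxin-linked and oxoacid oxidoreductase genes, 10 fell and none rose (12 and 0 adjusted over the list alone, percentile 0.1, feather library A 0.38 above B), with FIAW1_03690 at -2.17 ± 0.21 (limma adjusted p = 0.029). Of 17 glycolysis and gluconeogenesis genes, 6 fell and 2 rose (9 and 3 adjusted over the list alone, percentile 0.3, feather library A 0.65 above B), with the phosphoglycerate kinase gene FIAW1_03380 down from 9386 to 1903 FPKM (-2.81 ± 0.45, limma adjusted p = 0.034). Of 70 flagella and chemotaxis genes, 17 rose and none fell (26 and 1 adjusted over the list alone, percentile 100). Here too the list includes branched-chain amino acid transport genes, and its member furthest apart was FIAW1_20900, of the amino acid transporter list. Of 36 peptidase genes, 3 rose and none fell, over all genes and adjusted over the list alone (percentile 64.5). Of 39 sugar transporter genes, 6 rose and 1 fell (14 and 7 adjusted over the list alone, percentile 25.9), and of 33 peptide transporter genes 1 rose and 2 fell (10 and 4 adjusted over the list alone, percentile 98.7). Of 21 amino acid transporter genes, 7 rose and none fell (8 and 0 adjusted over the list alone, percentile 99.0), and of 32 glycoside hydrolase genes 1 rose and 1 fell (0 and 0 adjusted over the list alone, percentile 9.8, feather library A at -0.34 relative to B).

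By FPKM, 521 of 2131 genes were at least 2-fold higher on feather than on tryptone and 84 at least 2-fold lower, and the authors' RLE values gave 331 and 156. By limma 129 rose and 142 fell (352 and 92 with library totals), and the authors' deposited table holds 421 and 347 at a DESeq2 FDR under 0.05 and 412 and 233 by edgeR. Without tryptone library A limma called 0 genes in either direction (321 at an unadjusted p under 0.05), without tryptone library B 7 and 10, without feather library A 670 and 645, and without feather library B 417 and 423. Every gene named here as past the test lost its call without tryptone library A.

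The sixth comparison set the digests against each other. The UDP-N-acetylglucosamine dehydrogenase gene FIAW1_00920 (2.56 ± 0.13, SE, limma, n = 2 libraries per condition, adjusted p = 0.0057), the ribose transport gene FIAW1_01900 (2.46 ± 0.18, adjusted p = 0.0089), and FIAW1_20610 and FIAW1_20630 (2.38 ± 0.45 and 2.35 ± 0.31, adjusted p = 0.04 and 0.021) rose on peptone relative to tryptone. On the other side, the pyruvate kinase gene FIAW1_13010 fell by 1.23 ± 0.21 (limma adjusted p = 0.033). FIAW1_05860, annotated for trehalose synthesis, had the largest deficit in log2(FPKM + 1) among genes with a product name, at 214 against 1701 FPKM. It stood at 3167 and 235 FPKM in the tryptone libraries and did not pass (limma adjusted p = 0.32). FIAW1_05850 and FIAW1_05840 did not pass either (limma adjusted p = 0.39 and 0.27). Of 39 sugar transporter genes, 18 rose on peptone and none fell (26 and 1 adjusted over the list alone, percentile 100). Of 33 peptide transporter genes, 7 rose and none fell (14 and 0 adjusted over the list alone, percentile 100), of 21 amino acid transporter genes 10 rose and 3 fell (11 and 5 adjusted over the list alone, percentile 100), and of 32 glycoside hydrolase genes 5 rose and 1 fell (10 and 2 adjusted over the list alone, percentile 99.5). Of 28 genes of aminotransferases and amino acid breakdown, 11 rose and none fell (15 and 1 adjusted over the list alone, percentile 100). Of 49 ribosomal protein genes, 7 fell and none rose (10 and 0 adjusted over the list alone, percentile 0.0).

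By FPKM, 137 of 2092 genes were at least 2-fold higher on peptone than on tryptone and 16 at least 2-fold lower, and by limma 181 rose and 40 fell (159 and 163 with library totals). The number that fell by limma was 17 without peptone library A and also 17 without peptone library B, and the number at least 2-fold lower by FPKM ranged from 18 to 29 with 1 library left out. Of the 181 and 40 limma calls, 87 and 4 were kept both without peptone library A and without B, and 155 and 9 both without tryptone library A and without B.

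Across all 4 conditions, in comparisons that share the feather libraries, 5 genes stood highest on feather by their smallest difference to the other 3. These were FIAW1_11150, FIAW1_18910, FIAW1_18920 and the genes of the hypothetical proteins FIAW1_01400 and FIAW1_01510. The smallest log2 FPKM differences were 8.27, 5.08, 4.53, 4.44 and 4.37. By limma FIAW1_18910 and FIAW1_18920 passed against all 3, FIAW1_11150 against peptone only (adjusted p = 0.062 and 0.082 against glucose and tryptone), FIAW1_01510 against glucose only (adjusted p = 0.13 and 0.084 against peptone and tryptone) and FIAW1_01400 against none (adjusted p = 0.055, 0.1 and 0.1). FIAW1_01510 held 41 counts on feather and 0 on glucose, at least 24.1-fold higher with 3 counts per condition as the floor. It stood at 6.2 and 59.8 FPKM in the feather libraries, and FIAW1_01400 at 18.7 and 108 FPKM. The 5 genes furthest below all others were FIAW1_17850, FIAW1_19310, FIAW1_08830, which has no annotation line, FIAW1_09130 and the hydrogenase subunit gene FIAW1_08840. The closest of the other conditions lay above feather by log2 differences that gave -3.19, -2.96, -2.95, -2.58 and -2.57 for feather. FIAW1_08840 stood at 867 FPKM on feather and 6876 on glucose and did not pass against glucose (-3.72 ± 1.27, limma, adjusted p = 0.086) or tryptone (adjusted p = 0.07), and FIAW1_19310 did not pass against tryptone (limma adjusted p = 0.05 after rounding). The other calls of these 10 genes against tryptone were lost without tryptone library A, where limma called 0 genes (321 at an unadjusted p under 0.05). Without a peptone library, the calls of FIAW1_08830, FIAW1_08840, FIAW1_11150, FIAW1_18910, FIAW1_18920 and FIAW1_19310 against peptone were lost, and without a glucose library those of FIAW1_01510, FIAW1_08830 and FIAW1_19310 against glucose (limma adjusted p up to 0.18 and 0.11).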

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

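The limma test and all of its alternatives, the list median with FIAW1_08300, and the use of single recovered libraries were chosen after the data were seen. The other alternatives were fixed before the data were examined. No paired analysis was possible because the columns carry no replicate numbers. With the authors' RLE values, the genes at least 2-fold lower were 70 for peptone against glucose and 81 for tryptone against glucose, and the higher and lower counts were 250 and 210 for feather against peptone and 331 and 156 for feather against tryptone. The authors' TMM values gave 71, 82, 266 and 196, and 345 and 144 in the same order, and median-of-ratios scaling of FPKM gave 66, 76, 243 and 215, and 329 and 161, with 10 lower for peptone against tryptone. These scalings take out the median difference of all genes in FPKM. A pseudocount of 10 also left 10 lower for peptone against tryptone, and a minimum of 50 FPKM left 115 higher for tryptone against glucose, where fewer genes were tested. A 4-fold threshold left, by its construction, 254 higher and 41 lower for feather against glucose, 138 and 19 for peptone against glucose, 86 and 24 for tryptone against glucose, 109 and 35 for feather against peptone, 129 and 19 for feather against tryptone, and 16 and 1 for peptone against tryptone.

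Limma counts with library totals were 1155 lower for peptone against glucose, 1019 lower for tryptone against glucose, 508 higher and 125 lower for feather against peptone, 352 and 92 for feather against tryptone, and 163 lower for peptone against tryptone. All 8 libraries in 1 fit gave 535 lower for feather against glucose, 327 lower for peptone against glucose, 362 higher and 245 lower for tryptone against glucose, 353 and 512 for feather against peptone, 469 and 537 for feather against tryptone, and 11 lower for peptone against tryptone. With 1 variance weight per condition in that fit, feather against tryptone had 324 and 311 and peptone against tryptone 313 and 137. With 1 variance weight per condition in the fit of a pair, the higher counts were 236 for feather against peptone and 245 for feather against tryptone. Limma-trend gave 245 higher and 221 lower for feather against tryptone. For these the cause was not tested. Calls of named genes were also gained. Of the genes named for feather against glucose, 10 that had not passed did so with 1 variance weight per condition and 10 with all 8 libraries in 1 fit. For feather against tryptone these numbers were 9 and 13, and for feather against peptone 4 and 3, with 1 call lost in the latter. A gene given as not passing there may therefore pass in another fit that keeps all libraries. Fits without a feather library take the spread from the other condition alone, so calls gained there do not bear on this.

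With each library left out in turn, limma counts ranged from 136 to 909 higher and from 36 to 921 lower for feather against glucose, from 488 to 821 and from 249 to 800 for peptone against glucose, from 363 to 791 and from 223 to 758 for tryptone against glucose, from 14 to 518 and from 44 to 483 for feather against peptone, from 0 to 670 and from 0 to 645 for feather against tryptone, and from 146 to 246 and from 17 to 50 for peptone against tryptone. Of the 181 higher and 40 lower calls of the last pair, 87 and 4 were kept both without peptone library A and without B, and 155 and 9 both without tryptone library A and without B. The count of 0 came without tryptone library A, with 321 genes at an unadjusted p under 0.05. By FPKM, the genes at least 2-fold lower for peptone against tryptone ranged from 18 to 29; the other 2-fold counts stayed within 1.5 times. No limma call changed sign with a library left out. With a library left out, the median of the ribosomal protein list relative to all genes ranged from -0.065 (without feather library A) to 0.666 for feather against glucose and from -0.489 to 0.201 (without feather library B) for feather against peptone. That of purine and pyrimidine synthesis ranged from -0.442 to 0.213 for feather against peptone and from -0.568 to 0.225 for feather against tryptone, both highest without feather library A. These 4 medians changed sign between the feather libraries, and the cause was not tested. Counting each list in each comparison and setting, 64 other medians moved beyond the replicate SD with a library left out and 436 did not, and under the other alternatives 14 moved and 580 did not. Some genes near the FPKM minimum may rest on few counts. In each library 97 or fewer genes had under 10 counts, among them the 60 genes at 0 in every condition.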

Other observations

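The tests of a share of other RNA, of a constant proportion of read-through and of the other mobile element genes, and the choice of the gene runs described next, came after the values had been seen.

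A run of 8 genes that includes the fatty acid synthesis genes already named, FIAW1_09100 to FIAW1_09170, was lower on feather than on every other condition: in comparisons that share the feather libraries, all 8 fell against glucose (log2 fold changes from -3.60 to -2.89, limma, adjusted p from 0.0023 to 0.0024), against peptone (-3.37 to -2.24) and against tryptone (-2.87 to -2.02). On peptone 1 of the 8 fell against glucose and on tryptone 3 did. The run also holds a gene of the biotin transporter BioY, FIAW1_09110, at 167 FPKM on feather and 1313 on glucose. The 4 phosphate transport genes FIAW1_18420 to FIAW1_18450 fell against glucose on feather (-4.33 to -2.65), on peptone (-1.59 to -0.82) and on tryptone (-2.48 to -1.86), and all 4 fell on feather against peptone (-2.64 to -1.76, limma adjusted p from 0.014 to 0.022), while none passed between feather and tryptone (-1.77 to -0.77). Without tryptone library A, limma called 0 genes between feather and tryptone, with 321 at an unadjusted p under 0.05, and the calls between feather and tryptone given here were lost.

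Another run of 4 genes set the digests apart. FIAW1_03530 to FIAW1_03560, with genes annotated as biotin synthase and the radical SAM protein ThiH, rose against glucose by 4.54 to 5.17 on peptone and by 4.59 to 4.96 on tryptone (limma, highest adjusted p = 5.9e-05 and 7.2e-06). On feather they rose by 0.71 to 1.08, and all 4 were lower on feather than on peptone (-4.40 to -3.46). FIAW1_03550 stood at 288 FPKM on glucose, 624 on feather, 7180 on peptone and 7203 on tryptone. In contrast the run FIAW1_04830 to FIAW1_04850 was higher on feather than on each digest, by 3.24 to 3.67 against peptone and by 3.20 to 3.56 against tryptone, where the calls were lost without tryptone library A (0 genes called, 321 at an unadjusted p under 0.05).

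The feather libraries lay further apart than those of any other condition. Library A was higher in the sulfur relay genes FIAW1_08320 to FIAW1_08370, where FIAW1_08320 stood at 4073 FPKM against 901 in library B, in the hydrogenase gene FIAW1_08850 (3601 against 563 FPKM), and in the ribosomal protein and the glycolysis and gluconeogenesis lists, whose medians both lay 0.65 above all genes on the log2 scale. With all 8 libraries thinned to 8464552 counts, 205 genes were still 2-fold apart in feather, against 47 in tryptone, 32 in peptone and 2 in glucose, which argues against depth, and taking out the trend with gene length left the scatter at 0.554. A share of RNA of another condition in library A would dilute feather genes alike, and the 6 genes under 10 FPKM elsewhere and at least 50 FPKM on feather had a scatter of 0.105, although their log2 FPKM ratios of A to B ranged from -2.53 to -1.30; the median ratio of -2.42 needs a share of 81.3%, while 20 genes at least 4-fold lower in library B than in each other condition allowed a median of 29.2% (4 of them allowed 81.3%), which leaves a smaller share open. A difference in growth stage or in the culture stays open, and no biological explanation was tested, since the labels name no difference between these libraries.

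The transposase gene FIAW1_11150 had 1793 and 4810 counts in the feather libraries and at most 2 in any other library. FIAW1_11140 and the flagellar gene FIAW1_11160, its neighbours by identifier order, were also higher on feather, by at least 1.70 (log2 FPKM) for FIAW1_11160, so read-through could contribute if they adjoin it, which was not checked on a genome. Read-through in a constant proportion would give 107.9 FPKM on glucose, where 0.04 was found. The other genes of the CRISPR and mobile element list did not rise as a set (median -0.13 relative to all genes), although 3 of them rose and 23 fell on feather against glucose. Growth on feather itself, a change of the element in that culture and reads shared with another copy stay open.

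The median FPKM of all genes was lower on peptone than on glucose (-0.37, log2), while the median-of-ratios scaled values were level by construction of that scaling. A few abundant genes could lower all others, since FPKM divides by the total. With the 20 genes of highest mean FPKM over both conditions out of the totals, the median was still -0.34. These 20 genes took 20.3% of the counts on peptone and 18.8% on glucose, so as a set they account for little of the difference. Because they were picked over both conditions, the test cannot decide about genes abundant on peptone alone. What else sets the difference was not tested.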
